A study of Mus musculus with 6 samples.

How the data were processed

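Adipose stromal cells (ASCs), the fibroblast-like progenitor cells of fat tissue, had been taken from the subcutaneous or the perigonadal depot (the visceral fat beside the gonads) of male mice and used without culture. Per the labels, the stromal vascular fraction was freed by mechanical and enzymatic digestion and sorted magnetically for cells without CD45 (a leukocyte marker) or CD31 (an endothelial marker) and with Sca1 (a stem and progenitor cell marker). Total RNA was labelled with biotin and hybridised to an Affymetrix array, 1 array per pool of cells, with 3 pools for each of the 2 depots. The labels give 6 animals and independent pools. They do not say whether 6 is the number for each pool or in all, nor whether the subcutaneous and perigonadal pools of 1 number came from the same animals, so p-values measure the spread between these pools.

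The value table deposited by the authors holds 1 normalized intensity per probe set and array on a linear scale, for 23531 probe sets (transcript clusters). Its scale was worked out from the values, since the log2 of the intensities averages to the log2 means of the authors' comparison table. The submitters' processing notes name Partek. Its version, the background correction and the normalization are not given in the sources used here. The medians of the arrays were close, at 6.92, 6.54 and 6.44 in subcutaneous pools 1 to 3 and 6.96, 6.55 and 6.51 in perigonadal pools 1 to 3, with maxima between 2102 and 2491. The number of arrays limits the precision. The authors' comparison table holds, per the file headers, the mean log2 intensity of each depot and their difference, the ratio of perigonadal to subcutaneous, a signed fold (a score that is minus the inverse of the ratio where that is below 1), the t score and the unadjusted p-value of a paired t-test by the authors, for 3694 probe sets at a p-value below 0.05.

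Gene names came only from this comparison table, so a probe set of the value table had a name here only if the authors' own test on these samples had selected it. That was so for 3541 of the 23531 probe sets (15.0%). Of the table's 3694 entries, 3417 were named through an accession in the RefSeq gene table of assembly GRCm38.p6, 166 through a symbol and 111 kept the symbol of the file. The current symbol differed from the file's in 269 cases. The table's gene description is shortened, so whether a probe set also covers a further gene is not known. Chromosomes and bands are those of the authors' table, which names no genome build. They are left out for genes where it gives none.

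Differences are perigonadal minus subcutaneous on the log2(intensity + 1) scale, which understates the change of dim probe sets. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with the pool number as a fixed block) over all 23531 probe sets with no filter, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The fit had 2 residual degrees of freedom and a prior worth 5.24. The block follows the study's own paired test. Recomputing a paired t-test on log2 intensities gave a p within 10% of the authors' value for 3435 of the 3541 matched probe sets when pools of the same number were paired, and for at most 335 under any other pairing. In the values themselves the pairing was weak. The deviations of same-numbered pools from their depot means correlated at 0.17, 0.16 and 0.053 across probe sets, which are not independent replicates.

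A set of 35 gene lists (654 entries) was written before the data were examined, as were the sample groups, the tests, all but 1 of the alternatives (3 others were extended to single genes afterwards) and the rule for naming genes. They cover regulators and subset markers of stromal cells, signalling and metabolic pathways, and markers of other cell types. Only 236 of their 632 distinct genes had a name here. Lists with at least 3 named members (31 of 35) were tested with limma's camera (preset inter-gene correlation of 0.01, adjusted over the 31 lists) on the brightest probe set of each of 3181 named genes. This departs from the plan, which was to test lists against all genes: each list is compared with other genes that the authors' test had selected. The text names the 12 genes with the largest positive and the 12 with the largest negative difference among those past the threshold and alike in direction in 3 of 3 pool pairs, and up to 4 members of each list, those with the largest differences among members past the threshold and then among the rest. No gene was passed over for a predicted or non-coding symbol. The named members of the sort marker list and of the Y-linked list are given in full. A few genes that this rule selects are not reported here.

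The fit was tested on simulated data. With 200 of 23531 probe sets changed in a simulated comparison of perigonadal with subcutaneous pools, it recovered 73% of those changed by a log2 value of 1 and 98% of those changed by 2, and 5 of its 176 calls were false. The simulated noise was independent between probe sets and arrays and had no pool effect. Far fewer probe sets were changed than the 2238 called in the data. The share of false calls therefore does not carry over to the data. For camera, lists were drawn from the probe sets with the lowest p-values on these same arrays. Of 200 random lists of 10, 3.5% had an unadjusted camera p below 0.05. Of lists drawn only from those higher in perigonadal pools, 100% did, which their choice made near certain. Random lists need not vary together as members of a real list may. The 3.5% therefore does not show how often real lists pass by chance. The alternatives were a fit with no replicate block, the methods' t-test, a trended robust prior, further quantile normalization, median centring, array weights, filters on dim probe sets, a pseudocount of 16, a threshold of 0.1, leaving out each pool pair or array, camera with an estimated correlation, and the mean of a gene's probe sets. A fit with no pseudocount was chosen after seeing the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Scan dates and other batch information were not used here.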

Results

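Gene expression was measured in freshly sorted ASCs of male mice on 6 Affymetrix arrays, 3 of pools from subcutaneous and 3 of pools from perigonadal fat. Each array gave a normalized intensity for 23531 probe sets. Across probe sets, the log2 intensities of arrays from the same depot correlated at 0.992 to 0.995 (Pearson) and those of arrays from different depots at 0.978 to 0.981.

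The single comparison of the design asks how ASCs of perigonadal fat differ from those of subcutaneous fat. Perigonadal ASCs had far higher levels of the transcription factors Tcf21 and Wt1, of the collagen VI chain Col6a5, of haptoglobin (Hp) and of the matrix proteins Matn2 and Hmcn1. Subcutaneous ASCs had far higher levels of the decoy interleukin receptor Il1r2, the matrix protease Mmp3, the steroid-metabolising enzyme Akr1c18 and the cell-surface peptidase Mme. In limma, 952 probe sets were higher and 1286 lower in perigonadal pools at an adjusted p below 0.05, each in the same direction in 3 of 3 pool pairs. Of these, 284 were at least 2-fold higher and 232 at least 2-fold lower. Among the 1832 of the 2238 changed probe sets that had a gene name, 667 distinct genes were higher and 1002 lower, with 205 and 219 of them changed at least 2-fold. The largest absolute log2 difference among the 406 changed probe sets without a name was 1.54. Without pool pair 1 the counts were 529 higher and 660 lower, and without pool pair 2 the number lower was 716. With the methods' t-test, which takes each probe set's spread from its 3 pairs alone, 1 probe set passed the Benjamini-Hochberg adjustment, and with a pseudocount of 16 the number changed at least 2-fold was 184.

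**Figure D1:**
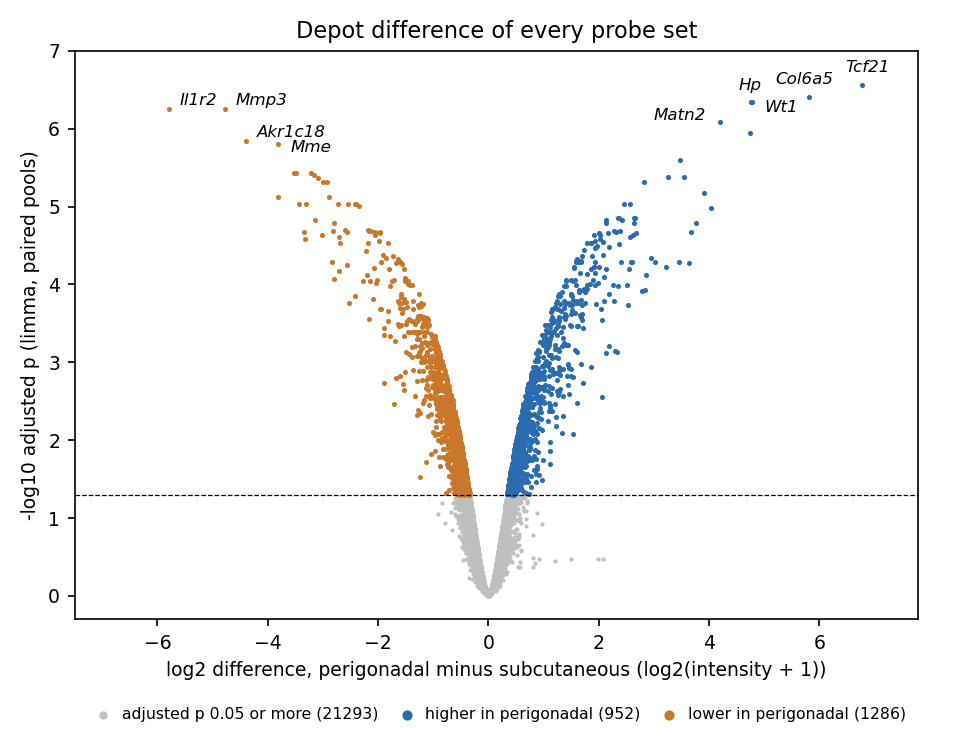
Log2 difference, perigonadal minus subcutaneous, of log2(intensity + 1) (horizontal) against -log10 of the limma adjusted p (vertical) for 23531 probe sets. The dashed line marks an adjusted p of 0.05; 952 probe sets lie above it on the right and 1286 on the left, with Tcf21 and Il1r2 farthest out.

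Tcf21, which specifies mesenchyme of the epicardium, kidney and other visceral organs, showed the largest difference of all named genes. Its normalized intensity (transcript cluster 10368240, chromosome 10, band A3) was 3.88 ± 0.351 in subcutaneous and 530.4 ± 10.5 in perigonadal pools (mean ± SD, n = 3 here and below), a log2 difference of 6.77 ± 0.092 (SE, adjusted p = 2.74e-07). The subcutaneous value was below the array medians, and over the alternatives the difference lay between 4.78 and 7.10. The size and order of differences of genes this dim in 1 depot depend on the pseudocount. Col6a5 (10596403, chromosome 9, band F1) rose from 6.99 ± 0.448 to 449 ± 24.8, a log2 difference of 5.81 ± 0.092 (adjusted p = 3.87e-07). Wt1, a zinc finger factor of the urogenital mesoderm and mesothelium (10474295, chromosome 2, band E), was at 4.18 ± 0.493 and 141 ± 13.5, a log2 difference of 4.78 ± 0.084 (adjusted p = 4.55e-07). Hp, which binds free haemoglobin (10581605, chromosome 8, band D3), was at 18.7 ± 0.662 and 533 ± 12.8, a log2 difference of 4.76 ± 0.084 (adjusted p = 4.55e-07). The matrilin gene Matn2 (10423599) was at 10.8 ± 0.405 and 216 ± 18.4, a log2 difference of 4.20 ± 0.087 (adjusted p = 8.14e-07). Hmcn1 and Hmcn2, which encode the hemicentins of the extracellular matrix, were higher by log2 3.76 ± 0.15 and 2.79 ± 0.18. Hmcn1 (chromosome 1, band G1) had 70 probe sets with its name here, all selected by the authors' own test, of which 69 passed the threshold and 62 were at least 2-fold higher. The remaining genes of the 12 were the cartilage matrix gene Cilp (log2 difference 3.45), the glutathione transferase Gsta3 (3.01, chromosome 1, band A4), the matrix gene Vwa1 (2.82, chromosome 4, band E2), the deaminase Rida (2.63) and thrombospondin 1, Thbs1 (2.58). Their adjusted p-values lay between 4.91e-06 and 5.19e-05, and that of Hmcn2 was 0.000121.

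Il1r2 showed the largest difference in the other direction. It binds interleukin 1 without signalling, and its intensity (10345752, chromosome 1, band B) was 440.4 ± 34.9 in subcutaneous and 6.96 ± 0.715 in perigonadal pools, a log2 difference of -5.79 ± 0.11 (adjusted p = 5.61e-07). Mmp3, the matrix protease stromelysin (10583071, chromosome 9, band A1), was at 335 ± 8.54 and 11.3 ± 0.899, a log2 difference of -4.78 ± 0.09 (adjusted p = 5.61e-07). Akr1c18, an enzyme that inactivates progesterone (10407435, chromosome 13, band A1), was at 89.4 ± 6.49 and 3.32 ± 0.345, a log2 difference of -4.39 ± 0.10 (adjusted p = 1.45e-06). Mme, neprilysin (10492355, chromosome 3, band E1), was at 94.3 ± 4.23 and 5.84 ± 0.798, a log2 difference of -3.81 ± 0.091 (adjusted p = 1.56e-06). The alcohol dehydrogenase Adh7, which can oxidise retinol, also fell by 3.81 on the log2 scale, and the growth factor binding protein Igfbp5 (chromosome 1, band C3) went from 570 ± 27.3 to 49.0 ± 8.35, a log2 difference of -3.53. The others were the protocadherin Pcdh20 (-3.48, chromosome 14, band E1), the chemerin receptor Gpr1 (-3.43, chromosome 1, band C2), the chemokines Ccl8 (-3.34, chromosome 11, band C) and Cxcl13 (-3.33, chromosome 5, band E3), the interleukin 18 receptor Il18r1 (-3.30, chromosome 1, band B) and the odd-skipped transcription factor Osr2 (-3.22, chromosome 15, band B3.1). The adjusted p-values of these last 8 genes lay between 3.74e-06 and 2.65e-05.

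**Figure D2:**
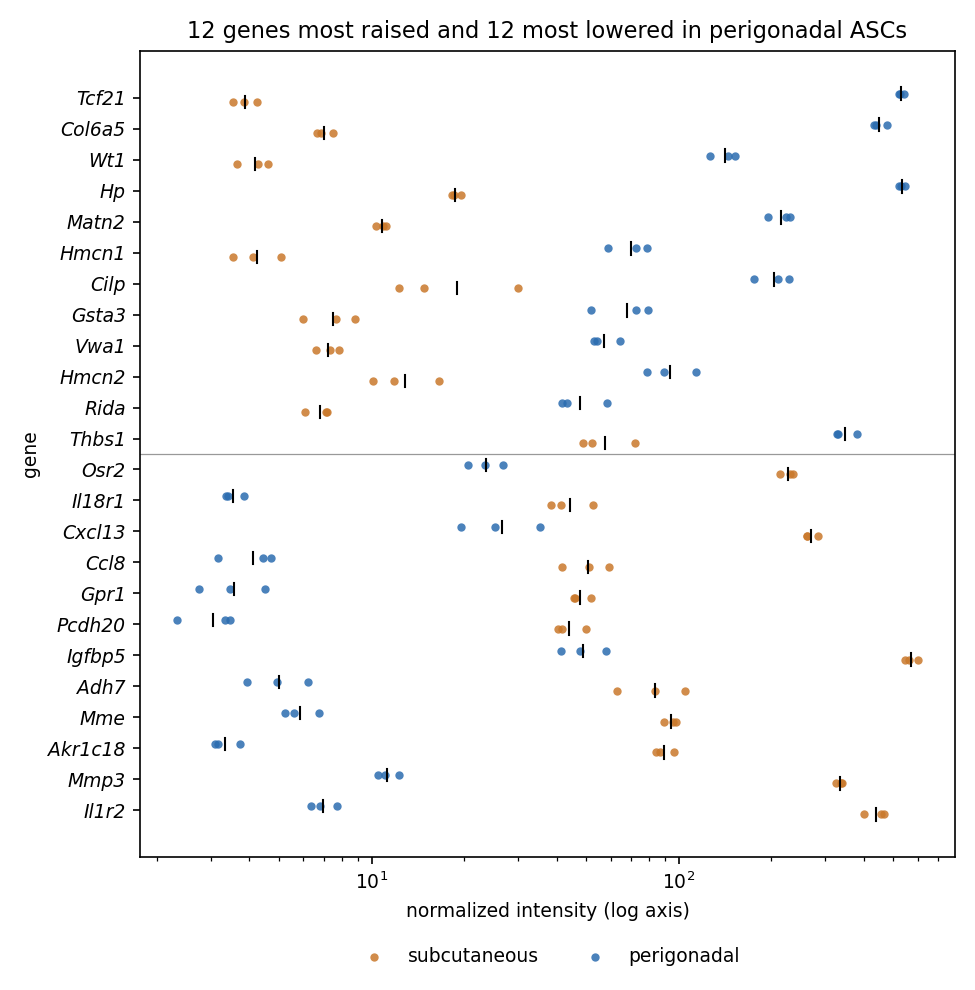
Normalized intensity (log axis) of the 12 genes most raised (upper block) and the 12 most lowered (lower block) in perigonadal ASCs, 1 point per pool in orange for subcutaneous and blue for perigonadal, with a black line at each mean of 3. For each of the 24 genes the points of the depots do not overlap, as with Tcf21 at 3.88 against 530.4.

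The gene lists were counted over named members only, and a gene had a name only where the authors' own unadjusted test on these samples had selected it, so the counts are not independent evidence of direction. Counts are given at an adjusted p below 0.05 over all probe sets. The count adjusted over the list alone is given where it differs from that. That adjustment covers only the named members, which the authors' test had already selected at a p below 0.05. It therefore corrects little, and the calls it adds are no further evidence. Camera compared each list with other named genes, whose median log2 difference was -0.17. By their brightest probe sets, 665 of the 3181 named genes were higher, 1000 were lower and 1516 did not pass.

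Of 4 named visceral developmental regulators, 3 were higher in perigonadal pools: Tcf21, Wt1 and the nuclear receptor Nr2f1, whose intensity was 8.04 ± 0.62 against 19.2 ± 1.86. The cardiac factor Tbx20 was at 2.32 and 2.46 (adjusted p = 0.782). This list passed camera with an adjusted p of 0.0193, and had an adjusted p of 0.704 with an estimated correlation. Wt1 is also a mesothelial marker, and the 10 named mesothelial markers had a median log2 difference of 1.77. Of 10 named subcutaneous developmental regulators, 8 were lower in perigonadal pools and 2 were higher. The limb factor Tbx5 was at 33.2 ± 1.83 against 3.48 ± 0.288, Tbx15 at 30.2 ± 0.352 against 3.49 ± 0.86, Hoxc10 at 41.8 ± 4.03 against 5.60 ± 0.914 and Shox2 at 30.8 ± 2.67 against 5.22 ± 0.402. The list had a camera adjusted p of 0.129, and of 0.0303 with no replicate block. Among 10 named HOX genes, which encode positional identity along the body axis, 6 were higher, 2 lower and 2 did not pass, with 7 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.129). Hoxa5, Hoxb5 and Hoxc4 were higher by log2 1.498, 1.13 and 0.67, while Hoxc10 had a log2 difference of -2.70.

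Of 11 named markers of Dpp4+ interstitial progenitors, an early stromal population, 10 were lower in perigonadal pools with a median log2 difference of -1.02, and 1 did not pass. Wnt2 was at 28.4 ± 2.5 in subcutaneous and 3.87 ± 0.507 in perigonadal pools, Dpp4 itself at 342 ± 14.3 and 118 ± 7.5, Bmp7 at 63.4 ± 5.74 and 21.3 ± 3.73, and Stmn4 at 42.5 ± 8.15 and 16.5 ± 5.17. The list passed camera with an adjusted p of 0.0352, but had 0.704 as its adjusted p with an estimated correlation, and it did not pass with a pseudocount of 16. The 3 named Schwann cell markers were lower in perigonadal pools as well, with a median log2 difference of -1.45. Of 8 named markers of adipogenesis-regulatory cells, 5 were higher, among them Fmo2 (83.5 ± 14.9 against 258 ± 1.78), Mgp (329 ± 74.3 against 968 ± 68.8), the tissue factor gene F3 and Vit, and 2 were lower, with 6 higher when adjusted over the list alone (camera adjusted p = 0.129). Of 6 named markers of committed preadipocytes, 4 were lower, including the fatty acid transporter Cd36 (log2 difference -1.61) and the adipogenic receptor Pparg (-0.77), and 2 were higher, Lifr (1.01) and Ggt5 (0.82) (camera adjusted p = 0.667). Of 8 named adipogenic transcription factors, 5 were lower, led by Ebf3 with a log2 difference of -1.36, and none was higher. Adjusted over the list alone, 7 were lower and 1 was higher (camera adjusted p = 0.236). The call of Klf4 (-0.44), another member, was lost with no replicate block, with no pseudocount and with a pseudocount of 16. It was also lost without pool pair 1 or 2, and without any 1 of the 6 arrays. The fits without 1 array had no replicate block either, so their losses cannot be put down to the array left out. The Klf4 differences in these fits lay between -0.52 and -0.31. Only 3 of 16 brown and beige adipocyte genes had a name. The mitochondrial Cox8b (55.05 ± 11.0 against 5.29 ± 1.12) and the beige marker Tmem26 (35.6 ± 6.45 against 6.55 ± 0.7) were lower. Prdm16 joined them when adjusted over the list alone (camera adjusted p = 0.165). The 3 named mature adipocyte markers had a median log2 difference of -0.60, with 2 lower and 3 lower when adjusted over the list alone. The 4 named mesenchymal stromal markers went both ways, 2 higher and 2 lower, with Thy1 at 736 ± 22.7 against 378 ± 11.6 and Vcam1 higher by log2 0.57. Without pool pair 1 the Vcam1 difference was 0.48 and no longer passed. That list had a median log2 difference of 0.034, a mean of -0.081 and an upward camera direction (adjusted p = 0.839).

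Matrix genes changed in both directions. Of 13 named fibrillar and basement membrane collagens, 8 were lower and 3 higher, with 9 lower when adjusted over the list alone (camera adjusted p = 0.564). The main fibrillar chain Col1a1 was at 498 ± 65.0 in subcutaneous and 230.0 ± 12.4 in perigonadal pools and Col12a1 had a log2 difference of -0.95, while Col8a1 and Col4a6, chains of network-forming collagens, were higher by log2 1.86 and 1.23. Of 13 named matrix remodelling enzymes and inhibitors, 6 were higher and 5 lower, and 7 and 6 when adjusted over the list alone (camera adjusted p = 0.661). The aggrecanase Adamts4 was higher by log2 1.64, and Mmp3 and the gelatinase Mmp2 had log2 differences of -4.78 and -0.89. The median of this list was 0.24 and camera gave it an upward direction, while its mean was -0.18.

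Of 13 named interferon-stimulated genes, 11 were lower, 12 when adjusted over the list alone, and none was higher, with a median log2 difference of -0.95. Usp18 was at 46.9 ± 6.45 in subcutaneous and 9.25 ± 0.761 in perigonadal pools, Ifit1 at 40.6 ± 2.3 and 12.1 ± 3.2, Bst2 at 183 ± 44.2 and 71.4 ± 10.5, and Ifit3 at 87.2 ± 13.7 and 35.8 ± 8.68. The list passed camera with an adjusted p of 0.0193, and its adjusted p with an estimated correlation was 0.704. The 3 named leukocyte markers had a median log2 difference of 0.037. Of 16 named chemokines and inflammatory cytokines, 7 were lower and 5 higher, and 10 and 6 when adjusted over the list alone (camera adjusted p = 0.661). Beside Ccl8 and Cxcl13, the interferon-induced chemokine Cxcl9 fell by 2.53 and Cxcl14 fell by 2.40 on the log2 scale. Of 8 named complement genes, C4b (305 ± 10.04 against 50.9 ± 8.24), C2 and Cfb were lower and 1 gene was higher, with 2 higher when adjusted over the list alone (camera adjusted p = 0.911).

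Signalling lists also split. Of 12 named Wnt ligands and modulators, 8 were lower, 9 when adjusted over the list alone, and 3 were higher (camera adjusted p = 0.275). The antagonist Dkk2 was at 98.8 ± 12.6 in subcutaneous and 12.4 ± 0.287 in perigonadal pools, and Sfrp2 at 604 ± 20.8 and 205 ± 13.6. The agonist Rspo1, which is also a mesothelial marker, was at 15.97 ± 2.82 and 96.3 ± 14.3. Related genes, picked after their values were seen, went both ways. Sfrp1 and Rspo3 were higher by log2 1.55 and 1.49, while Rspo2 had a log2 difference of -0.77 and the ligand Wnt2 of -2.60. Antagonists and agonists thus did not part by direction. Of 15 named genes of BMP, TGF-beta and activin signalling, 6 were higher, such as Inhbb (log2 difference 1.57) and Bambi (1.31), and 5 were lower, such as Bmp7 (-1.54), with 7 and 6 when adjusted over the list alone. This list had a median of -0.13, a mean of 0.048 and an upward camera direction (adjusted p = 0.636). Of 10 named IGF and FGF signalling genes, 5 were lower, 7 when adjusted over the list alone, and 3 were higher (camera adjusted p = 0.564). Igfbp5 led the list, Fgf7 and Ghr had log2 differences of -0.94 and -0.82, and Fgf1 was higher by log2 0.99. Of 12 named genes of retinoid metabolism and signalling, 5 were higher and 4 lower. Aldh1a2, which makes retinoic acid from retinaldehyde and is also a mesothelial marker, and Rdh10, which oxidises retinol, were higher by log2 1.96 and 1.86, whereas Adh7 and Dhrs9, which can also oxidise retinol, had log2 differences of -3.81 and -1.57. The median of that list was -0.023 and its mean -0.12, against an upward camera direction (adjusted p = 0.636).

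Of 10 named glycolysis genes, 5 were higher in perigonadal pools, 8 when adjusted over the list alone, and 1 was lower. The lactate dehydrogenase subunit Ldhb was at 18.7 ± 1.02 in subcutaneous and 62.0 ± 6.86 in perigonadal pools and the glucose transporter Slc2a1 at 29.8 ± 3.63 and 67.8 ± 5.3, while the lactate transporter Slc16a1 was lower at 28.8 ± 5.25 and 13.7 ± 1.35. The median log2 difference was 0.38 and the camera adjusted p was 0.0193. Its adjusted p with an estimated correlation was 0.704. The 10 named mesothelial markers were higher in the same pools, with a median log2 difference of 1.77. Of 10 named antioxidant genes, 3 were higher and 2 lower, and 5 and 4 when adjusted over the list alone, led by the glutathione transferases Gsta3 and Gsta4 (log2 differences of 3.01 and 1.11, camera adjusted p = 0.452). Only 3 oxidative phosphorylation genes had a name, of which 1 was higher and 1 more was lower when adjusted over the list alone. The median of the list was -0.11, its mean 0.11 and its camera direction upward (adjusted p = 0.957). Of 4 named proliferation genes, Cdk1 was higher at 5.66 ± 0.412 against 8.70 ± 0.987, with 2 higher when adjusted over the list alone (camera adjusted p = 0.129). Without pool pair 2 the Cdk1 difference was 0.53 and no longer passed. Of 7 named dissociation and immediate early genes, which respond to tissue digestion and stress, 3 were higher, Nr4a2, Hspb1 and Egr2 with log2 differences of 1.79, 1.05 and 0.86, and 2 were lower. Adjusted over the list alone the counts were 4 and 3 (camera adjusted p = 0.564).

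Markers of other cell types were read in the same way. All 10 named mesothelial markers, genes of the cell layer that covers visceral fat, were higher in perigonadal pools. Besides Wt1 and Rspo1, Upk3b was at 3.55 ± 0.319 in subcutaneous and 22.04 ± 9.19 in perigonadal pools and Nkain4 at 7.98 ± 1.99 and 37.1 ± 12.8. This list passed camera with an adjusted p of 0.000343, and its adjusted p with an estimated correlation was 0.704. The 3 named Schwann cell markers were lower, with S100b at 21.4 ± 1.49 against 7.21 ± 1.13 and Mbp at 18.3 ± 0.143 against 7.03 ± 0.157 (camera adjusted p = 0.129). Of 7 named mural and smooth muscle markers, 5 were higher, including Des (8.78 ± 2.47 against 54.9 ± 6.81) and Acta2 (12.3 ± 4.39 against 36.4 ± 12.8), and the pericyte channel genes Abcc9 and Kcnj8 were lower, with log2 differences of -2.07 and -0.92 (camera adjusted p = 0.234). Of 3 named leukocyte markers, the dim Fcer1g was higher at 3.23 ± 0.471 against 6.40 ± 0.832 and the rest did not pass (camera adjusted p = 0.636). Of 3 named endothelial markers, Eng and Lyve1 were higher by log2 0.54 and 0.53, and Tek was lower at 130.0 ± 8.99 against 76.5 ± 2.94 (camera adjusted p = 0.564). The Eng call did not hold without pool pair 1, at 0.54, nor the Lyve1 call without pool pair 2, at 0.52. Of 3 named mature adipocyte markers, Plin4 (log2 difference -1.44) and Scd1 (-0.60) were lower, and Acaca (-0.25) passed too when adjusted over the list alone (camera adjusted p = 0.236). Without pool pair 1 the Scd1 difference was -0.57 and no longer passed. Of 3 named skeletal muscle markers, Actn3 was higher by log2 1.71. The median of the 3 was -0.09, their mean 0.47 and their camera direction upward (adjusted p = 0.928). Of 3 named surface epithelial and keratinocyte markers, Krtdap was lower at 131 ± 18.9 against 25.1 ± 10.8, with 2 lower when adjusted over the list alone (camera adjusted p = 0.636). A single epididymal and testicular marker was named, Lcn5, at 4.26 ± 0.245 and 3.82 ± 0.212 (adjusted p = 0.478), and no erythroid marker was.

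**Figure D3:**
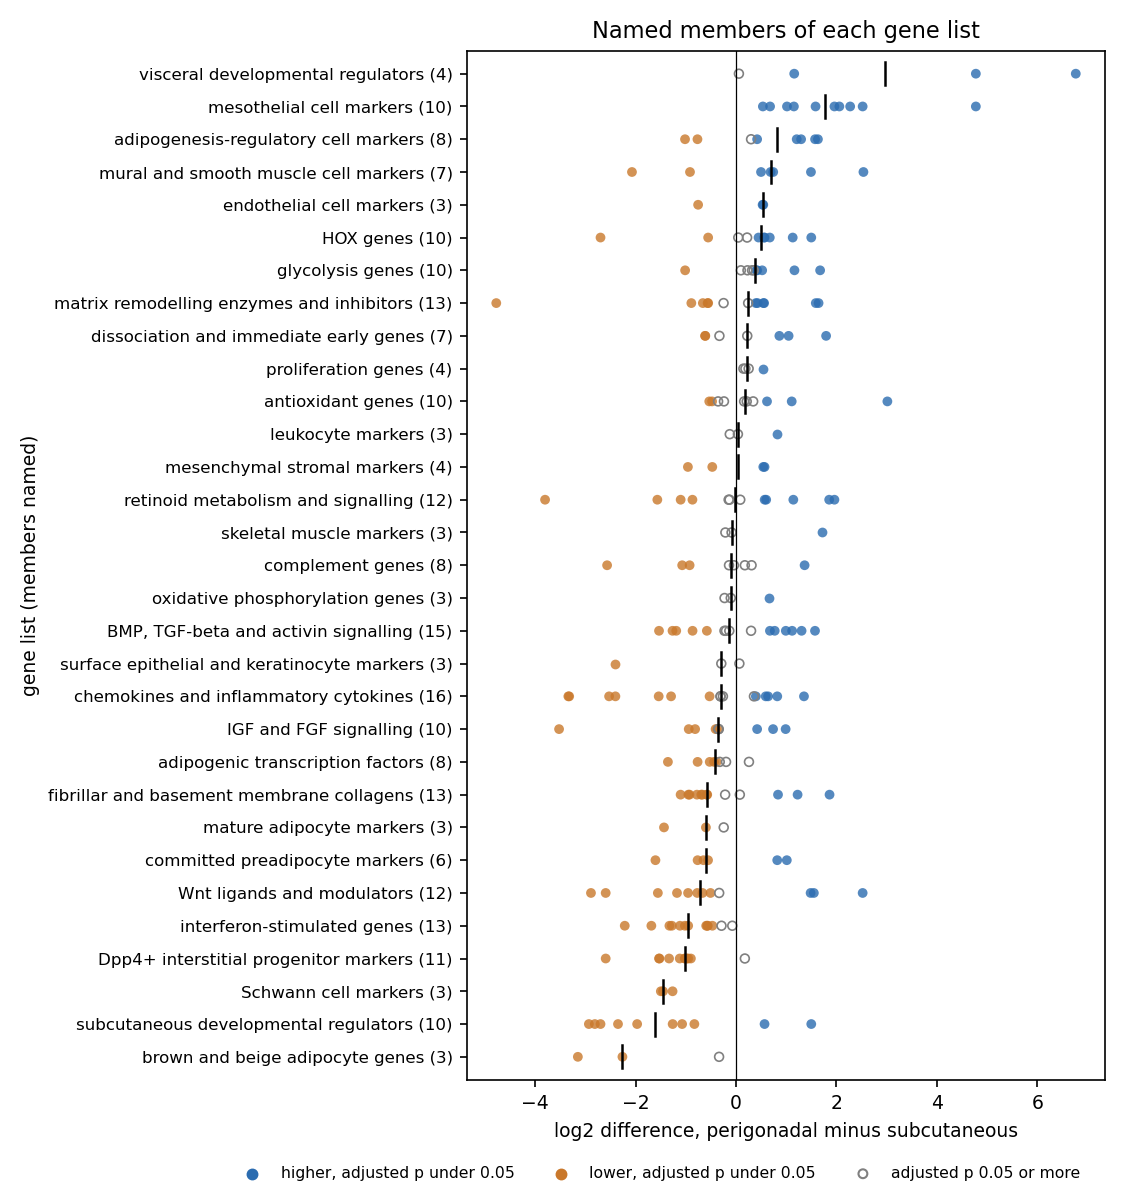
Log2 difference, perigonadal minus subcutaneous (horizontal), of each named member of the 31 gene lists with at least 3 named members, ordered by median. Filled points have a limma adjusted p below 0.05 (blue higher, orange lower), open points do not, and black bars are list medians, such as 1.77 for the 10 mesothelial markers and -0.95 for the 13 interferon-stimulated genes.

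Of the sort markers, only the Sca1 gene Ly6a had a name here. It was at 552 ± 59.5 in subcutaneous and 479 ± 44.0 in perigonadal pools, a log2 difference of -0.20 ± 0.086 (adjusted p = 0.231). As the only named member of a list of 3, its unadjusted limma p of 0.04999 stayed unchanged when adjusted over the list alone. The genes of CD45 and CD31 were not analysed here. The 2 named members of the Y-linked list, Eif2s3y (30.8 ± 1.37 against 40.1 ± 2.99) and Ddx3y (55.5 ± 6.88 against 70.2 ± 5.95), had log2 differences of 0.37 ± 0.085 (adjusted p = 0.0367) and 0.34 ± 0.091 (adjusted p = 0.0646), and both passed when adjusted over the list alone. Outside the list, and picked after their values were seen, the dim Y-linked genes Srsy (2.33 ± 0.233 against 3.39 ± 0.28, adjusted p = 0.0441) and Gm20831 (3.52 ± 0.236 against 6.62 ± 1.35, adjusted p = 0.00668) were higher as well. So were both probe sets of Sly (log2 0.68 and 0.70) and 3 of 5 of Ssty1, while Ssty2 (log2 0.14) did not pass. Without pool pair 1 the Eif2s3y difference was 0.35 and no longer passed.

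In the authors' deposited table, 1589 entries were higher and 2105 lower in perigonadal ASCs at an unadjusted p below 0.05. All 3541 of its entries with a row in the value table had the same direction here, on the same arrays, and 1832 of them (51.7%) passed the limma threshold.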

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

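The authors' deposited table holds 153 entries that have no row in the value table and so entered no test here, 69 higher and 84 lower in perigonadal ASCs. They stand out because 11 of them differ by at least 2-fold in that table. The largest are 6030408B16Rik, with a perigonadal to subcutaneous ratio of 12.4 in the authors' deposited table, and Wt1os, the antisense transcript beside Wt1, with a ratio of 5.72. Among the others, the authors' deposited table gives Fyb2 a ratio of 2.79 and Ecrg4, a secreted peptide precursor, a ratio of 0.389. These 4 were chosen after their values were seen. Without array values, neither their spread nor an adjusted p was computed.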

How the results depend on the processing

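All 24 genes named for their size kept their direction and passed the threshold in each of their 18 alternatives. The methods' t-test was run for counts only and is not among these. After Benjamini-Hochberg it left 1 probe set higher and 0 lower, so nearly all of the 24 would lose their call under it. For single genes, the pseudocount of 16 and the 2 filters on dim probe sets were added after seeing the data. Over all named genes, 2243 values under alternatives kept direction and side of the threshold, 50 lost the call, 8 gained it and 3 reversed. The reversed ones never passed: Pax7 at 0.0288 without perigonadal replicate 3, and Cldn4 at -0.0132 without subcutaneous replicate 3 and at -0.00793 without perigonadal replicate 1, each with no replicate block. Lost calls were those of Klf4 (11 alternatives), Eif2s3y (8), Pdgfrb (7), Srxn1 (5), Vcam1 (4), Prdx6, Slc2a3, Cdk1 and Lyve1 (2 each), and Eng, Hoxb5, Ebf1, Gsta4, Dnajb1, Nkain4 and Scd1 (1 each). The fit with no replicate block gave 943 probe sets higher, 1316 lower and 516 at least 2-fold apart and shared 2043 calls (91.3%) with the blocked fit. It ended the call of Klf4 and added subcutaneous developmental regulators to the lists past the threshold, and changed no other call of a named gene or list.

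The methods' t-test gave 1521 probe sets higher and 2014 lower at its unadjusted threshold, but 1 higher, 0 lower and 1 at least 2-fold apart after Benjamini-Hochberg. It has 2 degrees of freedom per probe set and no pooled spread. A pseudocount of 16 left 184 probe sets at least 2-fold apart, as it shrinks the differences of dim probe sets by construction. With no pseudocount, chosen after seeing the data, the counts were 871 higher, 1105 lower and 583 at least 2-fold apart. With an estimated correlation, camera called 0 lists past the threshold, and 1 (mesothelial markers) had an unadjusted p below 0.05. A pseudocount of 16 also ended the call of the Dpp4+ list. Leaving out a pool pair, or an array with no replicate block, gave 529 to 1068 probe sets higher, 660 to 1408 lower and 498 to 552 at least 2-fold apart. The lowest counts were without pool pair 1 (529 higher, 660 lower), and without pool pair 2 the number lower was 716. The lists past the threshold stayed at 5 without each pool pair, and the 24 genes at 24. Quantile normalizing again gave 968 higher and 980 lower (49.7% higher in place of 42.5%). The median log2 difference of all probe sets was -0.010 as deposited, -0.0079 after quantile normalization and -0.018 after centring. Testing only probe sets with 1 gene symbol was not run, since names existed only for probe sets chosen on the outcome.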

Other observations

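Chosen after their values were seen, several further genes separated the depots. Il1rl2, the interleukin 36 receptor, was at 185 ± 15.6 in subcutaneous and 46.8 ± 4.16 in perigonadal pools (log2 difference -1.96), and the cytokine Il18 at 64.5 ± 4.93 and 14.6 ± 3.02 (-2.09). The oxidant-producing enzymes Nox4 and Duox1 fell by 2.16 and 1.96 on the log2 scale, and the vasoconstrictor gene Edn1 had a log2 difference of -2.15. Related matrix genes went opposite ways, with Thbs1 at a log2 difference of 2.58 and Thbs2 at -2.12. Col6a6 was higher by 1.56 beside Col6a5 at 5.81. The guidance factor Slit2 (2.47), transferrin Trf (2.56), the TGF-beta binding protein Ltbp4 (2.56) and the prostaglandin receptor Ptger4 (2.10) were higher. All of these passed limma's threshold.

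The tests below that were chosen only after the result was seen are the count of mesothelial markers, the Schwann cell and leukocyte comparisons and the HOX test.

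The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share below 0.05. For probe sets higher (952), lower (1286) and at least 2-fold apart (516), 1 split, the real one, gave a count as large, and the highest count of any other split was 4 for each. Every other split puts pools of both depots on both sides, and these fits kept the pool block. Where a split parts 1 pool pair, its effect is the depot difference of that pair alone. Where it parts all 3, the effect sets 1 pair against the others and keeps part of that difference. In each, the depot difference also widens the spread and lowers the counts. This contrast was thus partly fixed in advance, and the highest count of 4 is no chance count. For gene lists past the threshold, 3 splits, the real one included, gave as many as the real 5. The other splits gave from 1 to 5 lists. Those that tied with the real split each parted 1 pool pair, so their effect was itself a depot difference, in either sign. They are no chance comparison, and the number of lists passing camera decides nothing here.

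All 10 of 10 named mesothelial markers were higher in perigonadal pools, 3 of which (Wt1, Rspo1 and Aldh1a2) are also in other lists. A lower share of stromal cells raising every other cell type alike would have raised the Schwann cell markers. The median log2 difference of the 3 named of 12 was -1.45, which argues against a rise of all cell types alike. Medians of the other cell types with at least 3 named markers went both ways. They were 0.69 for mural and smooth muscle, 0.53 for endothelial and 0.037 for leukocyte markers. For mature adipocyte, surface epithelial and skeletal muscle markers they were -0.60, -0.29 and -0.09. A lower stromal share with unequal rises stays open. Mesothelial cells in the perigonadal sort stay open as a candidate source, since depletion of CD45 and CD31 would not remove them, though selection for Sca1 would remove those without it. If their share varied between pools, the markers would vary together over the 3 perigonadal pools, but the median correlation of their deviations was 0.0043, at the 47.8 percentile of random sets, which decides nothing. Wt1 was at 4.18 in subcutaneous and 141 in perigonadal pools and Rspo1 at 15.97 and 96.3, and expression of these genes by perigonadal stromal cells themselves, a depot difference, was not tested.

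The median log2 difference of the 13 named interferon-stimulated genes, 11 of them past the threshold and lower in perigonadal pools, was -0.93, -0.81 and -0.81 in the 3 pool pairs. A single subcutaneous pool with an interferon response would leave at least 1 pair near 0, and the smallest drop was -0.81. This cannot decide the question, because the authors' paired test on these same pairs had selected the 13 genes. That test would tend to leave out genes raised in 1 pool alone. The other members of the list of 20 had no name here, so nothing is said of them. Leukocyte RNA in the subcutaneous pools could bring such transcripts, although the sort depleted CD45 cells, and cannot be told apart, because only 3 leukocyte markers had a name, with a median log2 difference of 0.037. A difference in interferon tone between the depots stays open and untested.

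Genes that lie next to each other on a chromosome tended to change in the same direction. Among 1622 changed genes placed by the gene order of GRCm38.p6 (protein-coding genes of the table used here), 153 of 201 adjacent pairs (76.1%) shared a direction, against a median of 52.2% and a 95th percentile of 57.7% in 10000 shuffles of the directions (one-sided permutation p = 1e-04, the smallest these can give). Chance order is thus argued against. Tandem gene copies may share probes or regulation. Of the 171 pairs whose symbols do not share their first 3 letters, 73.7% had the same direction (permutation p = 1e-04 again). Copies with such like symbols are thus not the whole of it. The filter can keep related genes with unlike symbols, such as the complement genes Cfb and C2, so tandem copies were not fully set aside. Whether shared regulation of a region or transcripts that run from a gene into the next underlie this was not tested. Examples, chosen after their values were seen, are Laptm4b (1.32) beside Matn2 (4.20) on chromosome 15 and Bco2 (-1.10) beside Il18 (-2.09) on chromosome 9, while Tcf21 (6.77) and Eya4 (-1.44) on chromosome 10 went opposite ways.

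By paralog group, the order along the clusters, all 6 HOX genes past the threshold in groups 1 to 8 (Hoxa3, Hoxa5, Hoxb5, Hoxc4, Hoxc8 and Hoxd8) were higher in perigonadal pools and both in groups 9 to 13 (Hoxa9 and Hoxc10) were lower. The two-sided Fisher's exact test of this split gave p = 0.0357, but the boundary between groups 8 and 9 was drawn after the directions were seen, so that p is no evidence for it. Hoxd12 and Hoxa13 did not pass, at log2 differences of 0.22 and 0.044.

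Perigonadal pool 2 alone had 14 probe sets more than 2-fold above both other perigonadal pools, 7 of them more than 4-fold, against at most 2 for any other pool within its own depot. The extreme was probe set 10489458 at 301.6, against 2.55 and 2.63 in the other perigonadal pools and at most 3.15 in the subcutaneous pools. Perigonadal pool 1 had 50 probe sets more than 2-fold below both others. The authors' table gives no name for 10489458.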
